A study of Mus musculus with 96 samples.

How the data were processed

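Total RNA from frozen mouse tissue was extracted and sequenced as cDNA libraries by a service provider, per the labels' protocols. The submitters' processing notes name the genome build GRCm39 and DESeq2, with no version. The aligner, the counter and the gene annotation are not given in the sources used here. Whether counting used strand is not given either, so antisense and overlapping genes and close paralogs are uncertain. The reference genome at hand was of an earlier build, so no coordinates are given, and gene symbols are those in the tables.

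The authors deposited a table of estimated counts per gene, with 56941 gene rows and 96 libraries. Of the values above 0, 26.8% differed from a whole number by more than 1e-06, so the deposited values were treated as estimated counts, not whole read counts. The authors also deposited a table of normalised values, treated here as a signal. Of the genes over 50 counts in a library, 12.3% to 29.8% over the 96 libraries had a ratio of normalised to estimated value within 1% of that library's median ratio. In each library that signal therefore differs from the estimated counts by more than one factor, and it was used only for this check. Of the gene rows, 310 have an identifier but no gene name. They hold at most 0.113% of a library's count and were kept in the totals.

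Each column name holds a tissue code and a running number. The codes were read as the tissue labels they begin, and the number of columns per tissue equals the number of samples. No column name holds a genotype or a replicate number from the labels. Libraries were not assigned to genotypes by their order or by their values. The tests fixed before the data were examined were edgeR quasi-likelihood comparisons of each strain with WT, tests among genotypes, and gene list tests, and none of them was run. Correlations between the factors, and of genes detected with depth and mitochondrial share, were computed over the libraries of each tissue and then left out, because their permutation test treats libraries of unknown genotype as exchangeable. The rule for named genes covered the 4 factors, the possible insertion loci, and genes called in those tests. The factors and loci are reported by that rule, per tissue and not per strain. Other genes are named from lists fixed before the data were examined, or from a ranking by spread, and were chosen after their values were seen. The ranking took, per tissue, the 10 named genes with the largest difference between the 90th and the 10th percentile of log2(CPM + 1). It used genes with a median above 5 CPM and left out predicted, mitochondrially encoded and sex-linked genes.

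CPM was the estimated count divided by the library total, times 1000000. Of 639 genes in 56 lists, 635 matched a gene name in the table. List levels used a pseudocount of 1 CPM. A gene was counted as detected at an estimated count of 1 or more. The floor for a count of 0 was 3 counts, which covers counting error only, since reads without molecular identifiers are not independent molecules. Totals ran from 6624474 to 17882603, so that floor is 0.168 to 0.453 CPM. Among 637 pairs of libraries within a tissue, 0 were identical, and the lowest chi-square per gene with 20 or more counts was 6.24, well above sampling noise. The level calculation was tested on simulated data made from 15 kidney-like libraries with 56941 genes and 200 changed genes. The Pearson correlation of recovered with known levels was 1.0 and the slope was 0.955. The changed genes were drawn from those above 20 CPM and the noise was Poisson only. The test therefore does not cover short lists or lists with members near 0.

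Alternatives chosen after seeing the data were TMM scaling over all tissues, TMM scaling within a tissue, CPM without mitochondrially encoded genes, a pseudocount of 0.5 CPM, a level of 5 CPM, and small intestine without the 2 libraries above 50% mitochondrially encoded counts. TMM factors came from edgeR 4.0.16 in R 4.3.3 on estimated counts rounded to whole numbers. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.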

Results

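RNA was sequenced from 7 tissues of 2 month-old mice: kidney, liver, small intestine, heart, brain, skeletal muscle and spleen. The labels describe WT animals and 4 reprogrammable strains, named 4Fj, 4FsB, 4Fk and 4FsA, which are built for inducing the reprogramming factors in vivo. The labels list 33 groups of tissue and genotype, most with 3 samples. WT heart had 2 samples and 4Fj spleen had 1, and spleen was sampled only in WT, 4Fj and 4FsA. The 96 libraries comprised 15 each of kidney, liver, small intestine, brain and skeletal muscle, 14 of heart and 7 of spleen. Total estimated counts per library ranged from 6624474 to 17882603, with a median of 11317947. The expression tables name each library by tissue and a running number and give no genotype. Libraries were therefore not assigned to WT or to a strain, and no strain was compared with WT or with another strain. Values below are CPM, the estimated counts per 1000000 counts of the library, within a tissue, as the median and range over its libraries. A list level is the mean log2(CPM + 1) of the members of a gene list in a library. These ranges mix genotypes, and no p-value is given for them. In every tissue but small intestine they also mix libraries with and without Y-linked counts, as described below. Where leaving out the library at one end moved a limit of 1 CPM or more, or a list level before the log, by over 1.5 times, the next value or the value without the named libraries is given.

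The 4 reprogramming factors were measured first, since their induction is the subject of the series. Pou5f1, which encodes the pluripotency factor Oct4, was at 1 CPM or more in 6 of 15 kidney, 6 of 15 liver, 8 of 15 small intestine, 8 of 14 heart, 3 of 15 brain, 2 of 15 skeletal muscle and 2 of 7 spleen libraries. Its highest value was 199 CPM in liver and 139 CPM in small intestine. The highest Pou5f1 value was 18.5 CPM in kidney, 14.3 CPM in spleen, 13 CPM in heart, 6.45 CPM in skeletal muscle and 2.44 CPM in brain. Except in small intestine, a single library set this value, and the next was 83.4 CPM in liver, 9.11 in kidney, 2.4 in spleen, 4.11 in heart, 2.03 in skeletal muscle and 1.36 in brain. A Pou5f1 count of 0 allows up to 0.453 CPM in the shallowest kidney library, which was the shallowest of all libraries, by counting error only. Pou5f1 was at 5 CPM or more in 2 kidney, 1 heart, 1 skeletal muscle, 1 spleen and 0 brain libraries. In skeletal muscle, Pou5f1 was at 1 CPM or more in 7 libraries with TMM scaling over all tissues and in 4 without mitochondrially encoded genes. In brain, TMM scaling over all tissues left 1 library with Pou5f1 at 1 CPM or more.

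Sox2, a factor of pluripotent and neural stem cells, ranged from 0 to 320.3 CPM in liver and from 0 to 286 CPM in small intestine. It was at 1 CPM or more in 7 liver, 8 small intestine, 6 kidney, 8 heart, 4 skeletal muscle and 1 spleen libraries. With TMM scaling over all tissues the skeletal muscle number was 8, and at 5 CPM it was 1, while heart had 2 at 5 CPM. All 15 brain libraries had Sox2 between 27.4 and 42.6 CPM. Klf4 and Myc had counts in every library. Klf4, a zinc-finger factor of epithelial differentiation, had its highest tissue median in small intestine, with a median of 241 CPM (range 10.9 to 538). The lowest Klf4 values there, 10.9 and 30.7 CPM, came from the 2 libraries with over 50% mitochondrially encoded counts, and the other 13 ranged from 94 to 538 CPM. In liver Klf4 had a median of 6.53 CPM (range 0.505 to 341), and in heart Klf4 had a median of 69.4 CPM (range 38.1 to 139). Klf4 had a median of 17 CPM in kidney (range 6.8 to 49), 15.8 in skeletal muscle (range 3.27 to 42.5), 10.2 in spleen (range 7.49 to 61.1) and 9.46 in brain (range 3.69 to 14.3). The second-highest Klf4 value was 175 CPM in liver, 32.2 in kidney and 13.9 in spleen, and the second-lowest was 8.07 in skeletal muscle and 5.9 in brain. Myc, a growth regulator, ranged over 1.99 to 866 CPM in liver and 2.32 to 903 CPM in small intestine. The Myc median in small intestine was 46.2 CPM, and 73 CPM without those 2 libraries. Myc ranged from 5.07 to 110.1 CPM in kidney (median 13.8), from 2.19 to 44.5 CPM in heart (median 10.1) and from 0.972 to 64.2 CPM in skeletal muscle (median 5.54). In spleen Myc had a median of 71.5 CPM (range 52.3 to 137), and in brain Myc had a median of 5.13 CPM (range 1.97 to 8.78). The second-highest Myc value was 58.4 CPM in kidney, 27.3 in skeletal muscle and 85.6 in spleen, and the second-lowest in brain was 3.09. One row per gene was read, so transgene and endogenous transcripts were not separated here.

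**Figure D1:**
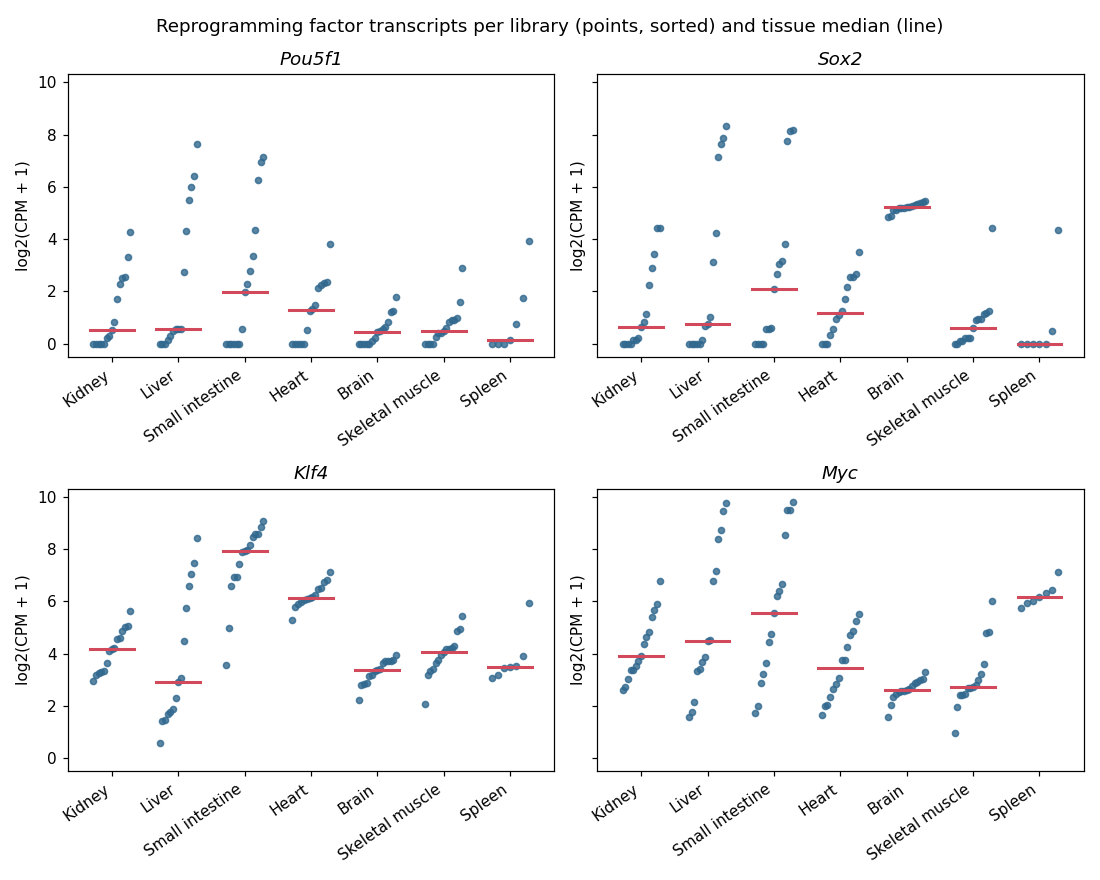
Each point is a library, sorted by value within its tissue, and the line is the tissue median. The vertical axis is log2(CPM + 1) and the horizontal axis is the tissue. The highest Pou5f1 values lie in liver and small intestine, at 199 and 139 CPM, and Sox2 is present in every brain library.

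Genes of the pluripotency network were mostly low. Of the 26 list members, 17 reached 1 CPM in at least one small intestine library, and 4 had a median of 1 CPM or more there. In each of liver, kidney and skeletal muscle 9 members reached 1 CPM in a library. In spleen 10 did, in brain 8 and in heart 5. Several of the members are also expressed in adult tissue, such as Tfcp2l1 in kidney, with a median of 313 CPM (range 140.4 to 472). Klf5, an intestinal crypt factor, was high in small intestine, with a median of 201 CPM (range 12 to 383), or 72.7 to 383 CPM without the 2 libraries of over 50% mitochondrially encoded counts. Members with a median of 0 and a wide range in small intestine were L1td1, up to 157 CPM, Tdgf1, up to 30.9 CPM, Fbxo15, up to 19 CPM, and Sall4, up to 12.3 CPM. The second-highest value was 63.6 CPM for L1td1, 6.85 for Tdgf1 and 2.22 for Sall4. In liver, Tdh had a median of 3.42 CPM (range 0 to 254), and L1td1 reached 25.6 CPM. Nanog, a core pluripotency gene, stayed at or below 0.361 CPM in every library. The list level had a median of 1.07 (range 0.51 to 2.22) in small intestine, with a lowest level of 0.83 without those 2 libraries, and 0.62 (range 0.32 to 1.31) in liver. With most members near 0, this level depends on the pseudocount: at 0.5 CPM its median was 0.29 in small intestine and -0.16 in liver. These named members, like the members named in the paragraphs below, were chosen after their values were seen.

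Liver libraries carried the hepatocyte genes at high level. The hepatocyte list level was 10.1 (range 8.36 to 11.1), and Alb, the plasma albumin gene, had a median of 55931 CPM (range 32793 to 97497). Acute phase genes spread widely: the list level was 6.24 (range 4.88 to 8.73). Both Saa1 and Saa2 encode serum amyloid A. Saa1 had a median of 765 CPM (range 24.1 to 17317) while Saa2 had a median of 178 CPM (range 15.6 to 17544). These near-identical genes can share reads. Lcn2, an iron-scavenging acute phase protein, ranged widely too, with a median of 142 CPM (range 4.13 to 3490). Fatty acid synthesis genes had a level of 6.97 (range 4.57 to 9.97). Scd1, the stearoyl-CoA desaturase, had the widest range among them, with a median of 2721 CPM (range 51.6 to 44471). Cholesterol synthesis had a level of 6.68 (range 5.81 to 8.14), xenobiotic metabolism 5.4 (range 4.1 to 6.88), fatty acid oxidation 5.75 (range 5.03 to 6.85), and fetal liver and progenitor genes 1.81 (range 1.2 to 3.36). Cell cycle genes had a level of 1.38 (range 0.76 to 4.16), with Mki67 from 0.193 to 49 CPM (median 2.68) and Top2a from 0.193 to 35.2 CPM (median 1.34). Ribosome biogenesis had a level of 4.93 (range 4.39 to 7.27). Several upper limits each rested on a single library, not necessarily the same one. The second-highest value was 10437 CPM for Saa2, 1354 for Lcn2, 15414 for Scd1, 17.5 for Mki67 and 14.1 for Top2a. It was 8.4 for the fatty acid synthesis and 3.04 for the cell cycle level. The second-lowest acute phase level was 5.51. The mitochondrially encoded share in liver was 3.75% to 33%.

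Small intestine libraries ranged over 6.53 in cell cycle level and 6.63 in ribosome biogenesis level, more than kidney, liver, heart, brain or skeletal muscle. Of these libraries, 2 stood apart in mitochondrially encoded counts, at 78.8% and 62.3%, with 9569 and 14139 genes detected. The first of them gave the lowest cell cycle and ribosome biogenesis levels, 0.54 and 1.6. Without both, the ranges were 5.48 and 5.39, still wider than in those tissues. Enterocyte genes had a level of 8.84 (range 2.07 to 11.42), and 9.92 without both, with the same range. Apoa4, an intestinal apolipoprotein, and Fabp2, an enterocyte fatty acid-binding protein, are examples: Apoa4 had a median of 896 CPM (range 4.91 to 19720) and Fabp2 had a median of 1792 CPM (range 3.17 to 8768). Lct, which encodes lactase, had the widest spread of all ranked genes in this tissue, with a median of 20.5 CPM (range 0.158 to 2778). Without the 2 libraries the medians were 100.1 CPM for Lct, 1899 CPM for Apoa4 and 16 CPM for Duox2, an epithelial oxidase gene. Antimicrobial genes had a level of 4.92 (range 1.99 to 8.16), with Reg3b from 18.4 to 18454 CPM (median 1094) and Duox2 from 0 to 2942 CPM (median 10.1). Paneth cell genes had a level of 4.12 (range 1.58 to 8.41), goblet cell genes 6.08 (range 1.41 to 7.61), intestinal stem cell genes 4.18 (range 1.02 to 4.85), enteroendocrine genes 2.44 (range 0.14 to 3.47) and fetal-like intestinal genes 3.46 (range 1.79 to 5.38). Without the 2 libraries the goblet cell median was 6.74, and the lowest levels were 2.88 for goblet cell, 2.52 for stem cell, 1.08 for enteroendocrine, 2.52 for fetal-like and 2.61 for antimicrobial genes. Lyz1, the Paneth cell lysozyme, ranged widely, with a median of 105 CPM (range 6.89 to 2168). At the lower end, the next value was 5.35 for the enterocyte level, 183 CPM for Apoa4, 113 CPM for Fabp2 and 17.3 CPM for Lyz1. At the upper end it was 1106 CPM for Lyz1, 7.24 for the Paneth cell and 7.22 for the antimicrobial level. Cell cycle genes had a level of 4.32 (range 0.54 to 7.08) and ribosome biogenesis genes 4.94 (range 1.6 to 8.23). The share of counts from mitochondrially encoded genes was 4.32% to 78.8%, and the number of genes detected was 9569 to 24432 per library. Defensin and Reg3 genes have close copies, so their separate values are uncertain.

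Kidney libraries carried proximal tubule genes at a level of 9.47 (range 8.25 to 10.27), distal nephron genes at 6.66 (range 5.74 to 7.33) and podocyte genes at 5.5 (range 4.47 to 6.61). Kap, a proximal tubule transcript, was abundant, with a median of 19340 CPM (range 2873 to 33300). Umod, the uromodulin gene of the thick ascending limb, was also high, with a median of 2105 CPM (range 638 to 6705). Kidney injury genes had a level of 4.17 (range 2.89 to 7.27). Spp1, which encodes osteopontin, had the highest values among them, with a median of 892 CPM (range 331 to 13969). The fibrinogen genes Fgg and Fga had the highest values of the acute phase list, with Fgg from 2.97 to 3676 CPM (median 28.8) and Fga from 5.5 to 3576 CPM (median 43.6). Lcn2, of the same list, had values with a median of 16.9 CPM (range 0.84 to 947). Fatty acid oxidation genes had a level of 6.12 (range 4.38 to 8.37), with Cyp4a14 from 7.56 to 4154 CPM (median 276). Adipocyte genes had a level of 3.79 (range 0.62 to 6.34), and the adipsin gene Cfd ranged up to 265 CPM. The mitochondrially encoded share was 10.1% to 45.5%. Leaving out the highest library, the upper limits were 9099 CPM for Spp1, 1883 for Fgg, 1994 for Fga, 320.5 for Lcn2 and 889.9 for Cyp4a14, and 7.37 for the fatty acid oxidation and 5.99 for the podocyte level. Leaving out the lowest, the lower limits were 10.6 CPM for Fga and 21.2 for Cyp4a14, and 5.12 for the fatty acid oxidation and 8.86 for the proximal tubule level.

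Heart libraries were close to one another in cardiomyocyte genes, at a level of 10.13 (range 9.72 to 10.46), and Myh6, the adult cardiac myosin heavy chain, had a median of 17862 CPM (range 10156 to 26854). Myh7, the slow myosin heavy chain, spread more widely, with a median of 1149 CPM (range 110.2 to 15872). Cardiac stress genes had a level of 8.1 (range 7.0 to 9.32). Atrial genes had a level of 3.17 (range 1.89 to 6.37), with Myl7 from 0.175 to 293 CPM (median 8.52) and Myl4 from 1.13 to 498 CPM (median 13.6). Fatty acid oxidation genes had a level of 4.0 (range 2.99 to 5.15), and Pdk4, which shifts fuel use from glucose to fatty acids, had a median of 711 CPM (range 128 to 3205). The second-highest heart value was 8443 CPM for Myh7, 107.6 for Myl7 and 163 for Myl4, and 5.62 for the atrial level, and the second-lowest for Myh7 was 212 CPM. The mitochondrially encoded share was 29.6% to 40.2%. Skeletal muscle libraries carried fast fibre genes at 12.49 (range 11.8 to 13.26), and Myh4, the fastest myosin heavy chain, had a median of 36357 CPM (range 11707 to 53272). Slow fibre genes had a level of 1.95 (range 0.91 to 6.45) and regeneration genes 1.74 (range 0.97 to 2.58). The atrophy list had a level of 5.06 (range 3.68 to 7.42). The ubiquitin ligases Trim63 and Fbxo32, which mark muscle atrophy, ranged widely, with Trim63 from 76.2 to 8310 CPM (median 348) and Fbxo32 from 86.3 to 4945 CPM (median 453). The metallothionein genes Mt1 and Mt2 also spread, with Mt1 from 6.05 to 1658 CPM (median 68.1) and Mt2 from 1.73 to 1039 CPM (median 27.3). The second-lowest muscle value was 129 CPM for Trim63, 11.3 for Mt1 and 2.94 for Mt2. The mitochondrially encoded share in skeletal muscle was 4.67% to 43.4%, and it enters the denominator of every CPM value.

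Brain libraries were close in neuron genes, at a level of 9.17 (range 8.35 to 9.43), oligodendrocyte genes, at 7.74 (range 7.22 to 8.53), and astrocyte genes, at 7.04 (range 6.72 to 7.72). Microglia genes had a level of 4.48 (range 3.72 to 6.11) and striatal genes 6.82 (range 5.98 to 7.78). Choroid plexus genes had a level of 3.54 (range 1.73 to 4.96), hypothalamus and pituitary genes 2.84 (range 0.28 to 5.39) and cerebellar genes 2.33 (range 1.95 to 4.86). Ttr, the transthyretin gene of the choroid plexus, ranged widely, with a median of 193 CPM (range 0.475 to 1729). The hypothalamic neuropeptide genes Pmch and Avp did too, with Pmch from 0 to 167 CPM (median 24.1) and Avp from 0.0894 to 100.4 CPM (median 29). Spleen libraries carried B and plasma cell genes at 9.44 (range 8.84 to 9.76) and T cell genes at 6.67 (range 6.3 to 7.34). Red pulp macrophage genes had a level of 6.83 (range 4.7 to 8.04) and platelet genes 3.33 (range 2.53 to 5.54). Erythroid genes had the widest range of the spleen lists, at 5.76 (range 2.99 to 10.61). The band 3 gene Slc4a1 of the red cell membrane is an example, with a median of 26 CPM (range 0.546 to 1488). The second-highest value was 362 CPM for Slc4a1, and in spleen 8.76 for the erythroid, 7.35 for the red pulp macrophage and 4.13 for the platelet level, and in brain 2.79 for the cerebellar level.

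Other lists were measured in every tissue, and their levels are given here for only some tissues, not picked by a fixed rule. Interferon response genes had their highest median in spleen, at 5.03 (range 4.38 to 5.44), and their lowest in brain, at 1.29 (range 0.95 to 2.26). The p53 response list had a level of 3.95 (range 2.3 to 5.24) in liver and 3.68 (range 1.55 to 5.89) in small intestine. Integrated stress response genes had their highest median in small intestine, at 5.01 (range 1.82 to 6.76). Their level was 4.18 (range 3.73 to 5.74) in liver and 3.68 (range 3.07 to 5.3) in skeletal muscle. Clock genes had a level of 6.16 (range 5.52 to 6.67) in brain and 3.85 (range 0.93 to 4.9) in small intestine. Without the 2 small intestine libraries of over 50% mitochondrially encoded counts, the lowest levels there were 2.44 for clock, 2.87 for p53 response and 3.82 for integrated stress response genes. Immediate early genes had a level of 3.63 (range 2.96 to 6.08) in heart, extracellular matrix genes 4.43 (range 3.82 to 6.37) in kidney, and myeloid genes 2.69 (range 1.93 to 5.1) in liver. The second-highest level was 5.77 for extracellular matrix genes in kidney, 3.87 for myeloid genes in liver and 4.71 for integrated stress response genes in skeletal muscle. Genes listed in advance as possible transgene loci were also read, without evidence of where the transgenes lie. Neto2 ranged from 29.8 to 109.7 CPM in brain (median 57.8) and from 4.1 to 37.2 CPM in spleen (median 6.66). Its highest value was 14.7 CPM in liver, 11.4 in small intestine, 7.2 in skeletal muscle, 6.09 in kidney and 2.32 in heart. A single library set the Neto2 limit in spleen and kidney, where the next values were 14.9 and 1.84 CPM. Pparg had medians of 10.02 CPM in heart, 6.01 in spleen, 5.77 in small intestine, 4.36 in skeletal muscle, 3.98 in kidney, 2.85 in brain and 2.53 in liver, and reached at most 16.9 CPM, in small intestine, where its median was 8.93 CPM without those 2 libraries. Col1a1 had medians of 79.1 CPM in spleen, 59.2 in heart, 50.4 in skeletal muscle, 46.7 in small intestine, 19.9 in kidney, 10.9 in brain and 7.76 in liver. Sp3 had medians of 105 CPM in spleen, 46.7 in small intestine, 44.8 in brain, 33.6 in kidney, 25.4 in heart, 24.9 in liver and 12.8 in skeletal muscle. Gt(ROSA)26Sor, the transcript of the Rosa26 locus, had medians of 22.7 CPM in spleen, 13.8 in small intestine, 9.36 in kidney, 7.96 in brain, 7.59 in liver, 3.45 in skeletal muscle and 3.38 in heart.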

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

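The alternatives reported here were all chosen after seeing the data. The alternatives fixed before the data were examined were not run, since each needs a genotype per library: DESeq2's size factors and its Wald test, no low-count filter, a fold-change threshold, fits of only the groups compared, the replicate block, the sex-linked covariate, leaving out each replicate, and an estimated correlation between genes. No paired analysis was possible because the columns carry no genotype and no replicate number from the labels. The values compared were tissue medians of list levels, Klf4 and Myc, and numbers of libraries with Pou5f1 or Sox2 at 1 CPM or more. A median was counted as moved when it changed by at least the standard deviation over all its tissue's libraries. A number of libraries was counted as moved when it changed by more than 1.5 times. Ranges were compared only for leaving out the 2 small intestine libraries.

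TMM scaling within a tissue moved 0 of 183 values. Its factors multiply to 1 within a tissue, so a tissue median is likely to move little, and the ranges were not recomputed. TMM scaling over all tissues moved 36 of 183, of which 30 were list levels. It took Pou5f1 at 1 CPM or more to 1 brain and 7 skeletal muscle libraries, and Sox2 to 8 skeletal muscle libraries. It took the median to 5.91 CPM for Klf4 in brain, to 3.21 CPM for Myc in brain and to 40.5 CPM for Myc in spleen. Leaving out mitochondrially encoded genes moved 14 of 183 values, of which 12 were list levels. It took Pou5f1 to 4 skeletal muscle libraries and the Klf4 median in heart to 102.4 CPM. A level of 5 CPM moved 7 of 14 numbers of libraries. Pou5f1 then stood in 2 kidney, 1 heart, 0 brain, 1 skeletal muscle and 1 spleen libraries, and Sox2 in 2 heart and 1 skeletal muscle libraries. A pseudocount of 0.5 CPM moved 28 of 155 list levels, the pluripotency level in all 7 tissues among them. Leaving out the 2 small intestine libraries above 50% mitochondrial counts moved 0 of 29 values, though the enterocyte median went from 8.84 to 9.92. The standard deviation used as the bound included both libraries and was 2.74 for the enterocyte level, so the bound was wide. Lct, Apoa4 and Duox2, whose medians without both libraries are given above, were not among the 29. The cause was not tested for the TMM changes; the other changes follow from the altered denominator, level or pseudocount. Few counts limit the precision of both low factors in many libraries. Pou5f1 had 5 counts or fewer in 8 kidney, 9 liver, 6 small intestine, 5 heart, 10 brain, 8 skeletal muscle and 5 spleen libraries. Sox2 did in 7 kidney, 7 liver, 4 small intestine, 4 heart, 0 brain, 7 skeletal muscle and 6 spleen libraries.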

Other observations

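Of the tests in this part, thinning to equal totals, both thinning ratios without 2 libraries, those without the library at each end, and the count of acinar genes with a shared highest library were chosen only after the result was seen.

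In 1 kidney, 1 liver, 1 heart, 2 brain, 1 skeletal muscle and 1 spleen library, the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no count. Xist, the transcript of the inactive X chromosome, was at 1117 CPM in that kidney library, 408 in the liver library, 172 and 194 in the brain libraries, 59.6 in the muscle library, 883 in the spleen library and 3.31 in the heart library. The heart library was thus low in Xist beside the others without Y-linked counts, but its value was the highest of the 14 heart libraries. It also had the fewest genes detected in heart, 16048 against 18094 in the next. The libraries without Y-linked counts all carry running number 1, and in brain 1 and 2, in the column names. The small intestine library of number 1 had Y-linked counts, as did all others of that tissue. The labels do not say whether a number marks one animal across tissues. Over the 15 liver libraries, the female-biased list level ranged from 0.18 to 7.27 and the male-biased level from 2.60 to 8.45. The liver library without Y-linked counts had the highest female-biased and the lowest male-biased level, and the next values were 2.86 and 5.34. The female-biased gene A1bg reached 2445 CPM there, against 11.1 CPM in the next library and a tissue median of 0.

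Pou5f1 values over the libraries of a tissue, sorted, had gaps but no stated grouping. In liver they were 0, 0, 0, 0.101, 0.222, 0.418, 0.483, 0.487, 0.494, 5.71, 18.7, 43.6, 63.4, 83.4, 199 CPM. In small intestine they were 0, 0, 0, 0, 0, 0, 0.479, 2.92, 3.82, 5.82, 9.3, 19.5, 75.5, 122, 139 CPM. In kidney they were 0, 0, 0, 0, 0, 0.165, 0.234, 0.423, 0.763, 2.31, 3.89, 4.79, 4.88, 9.11, 18.5 CPM. In heart they were 0, 0, 0, 0, 0, 0.44, 1.4, 1.52, 1.77, 3.38, 3.69, 3.96, 4.11, 13 CPM. In skeletal muscle they were 0, 0, 0, 0, 0.184, 0.324, 0.326, 0.397, 0.535, 0.786, 0.865, 0.876, 0.966, 2.03, 6.45 CPM. In brain they were 0, 0, 0, 0, 0, 0.082, 0.177, 0.358, 0.417, 0.496, 0.551, 0.762, 1.35, 1.36, 2.44 CPM. In spleen they were 0, 0, 0, 0.117, 0.688, 2.4, 14.3 CPM.

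Small intestine libraries differed in the number of genes detected, from 9569 to 24432. After each library was thinned to the same total of 9323440 counts, the highest number was 2.56 times the lowest, and after thinning to 3041535 counts outside the mitochondrial genome, it was 2.17 times the lowest (9566 to 20731 genes). For the library with the fewest genes, this argues against depth or mitochondrial reads as the whole cause. Over the 13 libraries at or below 50% mitochondrial counts the ratio was 1.62 before thinning and 1.61 at equal totals, and 1.28 both times without the library at each end, which argues against depth as the whole cause there too. At 3041535 counts outside the mitochondrial genome it was 1.43, and 1.19 without the library at each end. That depth came from a left-out library, and the shallowest of the 13 had 8016530 such counts. Thinning that far can itself narrow the ratio, so this does not decide on mitochondrial reads for these 13. Genotype stays open too and was not tested.

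Pancreatic acinar genes, which encode digestive enzymes, were near 0 in most small intestine libraries and high in one. All 11 members of the list had their highest value in the same library, where Ctrb1 was at 7711 CPM and Cela2a at 7661 CPM, against at most 0.107 and 0.262 CPM in any other library. Pancreatic tissue in that piece may be the source, as a hypothesis. A test over all 15 libraries had bounds written before its value but after the wide range was seen. The median pairwise Spearman rho of the members was 0.38, where 1000 random sets of 11 genes had a median of 0.36. This could not decide on the source, since a rank correlation gives little weight to a single high library. Most members lay near the floor in the other libraries, but the second-highest value was 21 CPM for Cela1 and 27.95 CPM for Clps. The list also ranged widely in 2 other tissues. Its level reached 5.05 in spleen (median 0.84, second-highest 3.22) and 4.51 in kidney (median 0.51, second-highest 3.04).

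Atrial genes ranged widely in heart. A varying share of atrium in the sampled piece was taken to require a median pairwise Spearman rho above 0.7 over the 7 members, a bound written before that value but after the wide range was seen. It was 0.4, with pairs from -0.21 to 0.97, and random sets of the same size had a 99th percentile of 0.38. This does not decide between a share of atrium and other sources, and genotype was not tested.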
